A study of Homo sapiens with 145 samples.

How the data were processed

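HT-1080 cells, an established human fibrosarcoma line, were exposed for 24 h to etoposide (ETP, a topoisomerase II poison), methyl methanesulfonate (MMS, an alkylating agent) or quercetin (QUE, a plant flavonol), each at 7 doses, or to the DMSO vehicle of the same chemical. Per the labels, RNA was extracted, amplified and labelled with biotin by a 3' in vitro transcription kit, and 145 Affymetrix arrays of the perfect-match-only kind were hybridised. The deposited values are log2 probe set summaries, which the authors made with GCRMA (background correction, quantile normalization and summarisation) in Partek. Versions of both and a genome build are not given. Array medians and upper quartiles of the 3 chemicals did not overlap, so the authors' normalization was taken as done separately for each chemical's experiment. Levels were compared across chemicals only between the vehicle groups.

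The table held 54613 probe sets, of which 40914 had 1 gene symbol in the platform annotation, 864 had several and 12835 had none. Symbols were checked by gene ID against RefSeq names, and 40858 of the 40914 were equal. A probe set was kept if its log2 value was at least 4 in at least 5 arrays, which left 27102. A group mean under 4 was not taken as above background, and the size of a change against it is uncertain. Of these, 4337 with no or several symbols were not named. The remaining probe sets were collapsed to 12070 genes by the probe set with the highest mean over all arrays. No count or read depth exists for arrays, so the number of arrays and their spread set the precision. The table held 0 control probe sets, so the planned measures of RNA integrity (3' against 5' control signals) and of the hybridisation spike-ins could not be computed. Array medians and upper quartiles were compared instead between each highest dose and its vehicle by 6 two-sided exact permutation tests, adjusted together. The authors' quantile normalization makes these measures nearly equal, so they cannot stand in for RNA integrity.

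Groups, doses and replicate numbers were taken from the sample titles. A replicate number occurred on 2 arrays of 1 group in 3 cases, and those arrays were averaged, which gave 142 replicates. The labels do not say that replicate numbers stand for separate cultures. Within a chemical, arrays of different groups with the same number deviated alike from their group means. The mean correlation of these deviations across genes was 0.50 for ETP, 0.51 for MMS and 0.40 for QUE, against -0.08, -0.10 and -0.07 between different numbers. At ETP 0.003 and 0.01 µM, MMS 1 to 300 µM and QUE 1 to 30 µM every dosed array correlated above 0.1 with the vehicle array of its number. A fit with the replicate number as a block was run for every dose and difference, and its count is printed beside the result where it moved by over 1.5 times. At the other doses at least 1 pair did not correlate above 0.1, at ETP 0.03 to 3 µM the lowest being number 2.

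Each dose was compared with the vehicle of its own chemical by limma 3.58.1 (lmFit and eBayes with a mean-variance trend) in R 4.3.3, with the package data.table (1.17.8), over all 8 groups of that chemical. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within the contrast and a fold change of at least 1.5. Genes changed at any dose were found with limma's moderated F-test over the 7 contrasts. Differences between chemicals at their highest doses were contrasts of contrasts in 1 fit of all arrays, called by the same limits. Overlaps of called genes used two-sided Fisher's exact tests against the 12070 tested genes. Figures were drawn with matplotlib 3.10.9.

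Lists of genes were p53-activated targets, G2/M and mitosis, G1/S and DNA replication, histone genes, homologous recombination and Fanconi anemia, base excision and direct repair, apoptosis regulators, the ATF4 integrated stress response, endoplasmic reticulum chaperones, heat shock proteins, NRF2 antioxidant genes, aryl hydrocarbon receptor targets, hypoxia and HIF targets, cholesterol and fatty acid synthesis, metallothioneins, NF-kB and secreted inflammatory factors, interferon-stimulated genes, immediate early genes, extracellular matrix and TGF-beta targets, ribosome biogenesis, epithelial markers, blood cell markers and housekeeping controls. Of the 23 lists, 21 had at least 5 measured genes and were tested at the 21 doses with limma's camera at a preset correlation of 0.01. The p-values were adjusted over these 441 tests together. The camera test with an estimated correlation and limma's fry were run as alternatives.

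The genes named were chosen by a rule. For each highest dose it took the 8 called genes with the largest rise and the 8 with the largest fall whose dosed arrays did not overlap the vehicle arrays, and up to 4 called members of each list. CDKN1A, MDM2, GDF15, CYP1A1 and HMOX1 were always named, and 1 further gene of the rule is not analysed here. At lower doses it took up to 3 called genes in each direction, and for each difference between chemicals the 5 largest in each direction. Members of the histone, metallothionein, HSPA1A and HSPA1B, and AKR1C families share near-identical sequence, so which member a probe set measured is uncertain. Genes named outside the rule are said to be so. The comparisons, tests, gene lists, the rule and the alternatives, save those said to be added later, were chosen before the data were examined.

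Alternatives were no fold threshold, at least 2-fold, no filter, a log2 value of at least 6 in 5 arrays, the mean of a gene's probe sets, every probe set tested on its own, quantile normalization over all arrays, arrays centred on their median, no trend, the replicate block, array weights, only the compared groups, arrays with a suffix in their title left out or given a covariate, repeated numbers kept separate, and each replicate left out in turn. Leaving number 2 out of every ETP and QUE group, and number 3 out of every QUE group, was added after seeing the data. The calling steps were tested on simulated data, drawn around the vehicle means with each gene's fitted spread, with changes set for 200 genes per chemical. The fits called 58 of 67 genes with a 2-fold change at ETP 3 µM, 65 of 67 at MMS 500 µM and 56 of 67 at QUE 100 µM. For 1.5-fold changes they called 27, 23 and 27 of 67. Of the 12070 genes, 1, 4 and 8 were called falsely. For differences of 2-fold or more between chemicals, 233 of 265, 229 of 264 and 231 of 264 were called, with 3, 25 and 22 false calls. With the p53-activated targets also moved up 1.5-fold, the list test called that list and 1 other list at each highest dose. Simulated values were drawn independently for each gene and array, while real arrays of the same number deviated alike. The false calls therefore cannot show the error in the real data, least of all for lists, whose genes can move together. Lists can share genes, such as FAS among p53-activated targets and apoptosis regulators, so their tests are not independent.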

Results

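Gene expression was measured in 145 arrays of HT-1080 cells after 24 h of exposure, 49 in the ETP experiment, 47 in the MMS experiment and 49 in the QUE experiment. Each experiment had 7 dose groups and 1 vehicle group, 24 groups in all. After repeated numbers were averaged, each group held 6 replicates, except ETP 0.01 µM and MMS 500 µM with 5. Array medians (log2) spanned 3.51 to 3.59 for ETP, 3.08 to 3.17 for MMS and 3.33 to 3.41 for QUE, and upper quartiles spanned 6.56 to 6.64, 5.68 to 6.01 and 6.22 to 6.48. Within MMS the upper quartile was lowest in the number 4 arrays (5.75 to 5.86) and in 500 µM number 3 (5.68). It was 5.88 or more in the other MMS arrays. In 6 two-sided exact permutation tests of these measures between a highest dose and its vehicle, the smallest p was 0.152, and every adjusted p was at least 0.826. Quantile normalization makes such measures nearly equal, so these tests say little about the samples. The number of arrays and their spread within a group limit the precision. No arrays were identical.

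The arrays labelled number 2 in the ETP and QUE experiments stood apart from the other numbers, most clearly at the 5 highest doses. The response of an array (its values minus those of the vehicle array with the same number) was correlated across genes with the mean responses of the other numbers, with number 2 always left out of the means. The array labelled ETP 3 µM number 2 correlated at 0.30 with the ETP 3 µM response and at 0.90 with the QUE 100 µM response. The array labelled QUE 100 µM number 2 correlated at 0.89 with ETP 3 µM and at 0.39 with QUE 100 µM. The other 5 numbers correlated with their own chemical's highest dose at 0.80 to 0.90 for ETP and at 0.55 to 0.93 for QUE. At the lowest doses number 2 correlated at 0.58 with its best QUE dose and 0.05 with its best ETP dose (ETP 0.003 µM), at 0.09 with ETP and 0.01 with QUE (QUE 1 µM) and at 0.38 and 0.05 (QUE 3 µM). Genes are not independent replicates, so no test was made of these correlations. All values below keep the arrays as labelled, and values without number 2 stand beside the counts of ETP and QUE and beside some of their genes.

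**Figure D1:**
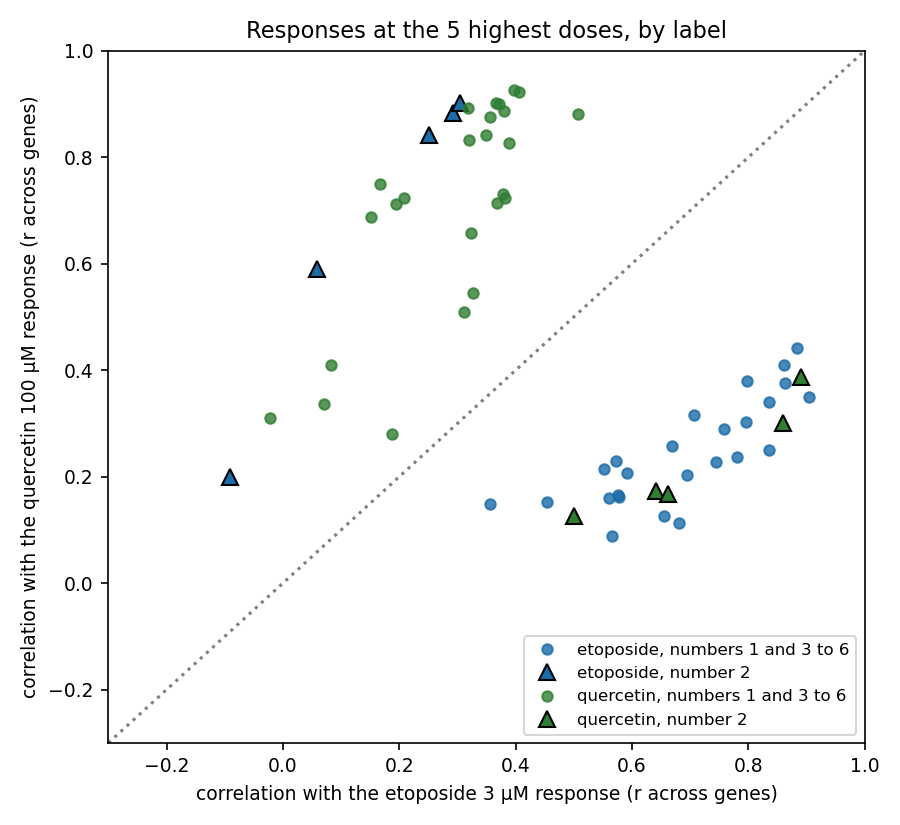
Correlation across genes of each array's response with the mean response at ETP 3 µM (horizontal axis) and at QUE 100 µM (vertical axis), for arrays at the 5 highest doses of ETP and QUE, with triangles for number 2. The triangle of ETP 3 µM lies at 0.30 and 0.90, and that of QUE 100 µM at 0.89 and 0.39.

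The first question was from which dose each chemical changed gene expression. ETP changed 14 genes at 0.03 µM (13 higher, 1 lower, and 41 called with the replicate number as a block), 136 at 0.1 µM (294 with the block), 379 at 0.3 µM, 821 at 1 µM and 1399 at 3 µM. The limma count was 0 at 0.003 and 0.01 µM, where 62 and 49 genes had an unadjusted p under 0.05. MMS changed 194 genes at 100 µM (295 with the block), 1474 at 300 µM and 4173 at 500 µM. For 1, 3, 10 and 30 µM of MMS the limma count was 0, with 32, 37, 59 and 127 genes at an unadjusted p under 0.05. QUE changed 24 genes at 10 µM (144 with the block), 1323 at 30 µM, 2273 at 60 µM, 2299 at 80 µM and 2713 at 100 µM. At QUE 1 and 3 µM the limma counts were 0, with 90 and 137 genes at an unadjusted p under 0.05, and 2 and 3 called with the block. Over all doses the F-test called 1321 genes for ETP, 4280 for MMS and 3013 for QUE.

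**Figure D2:**
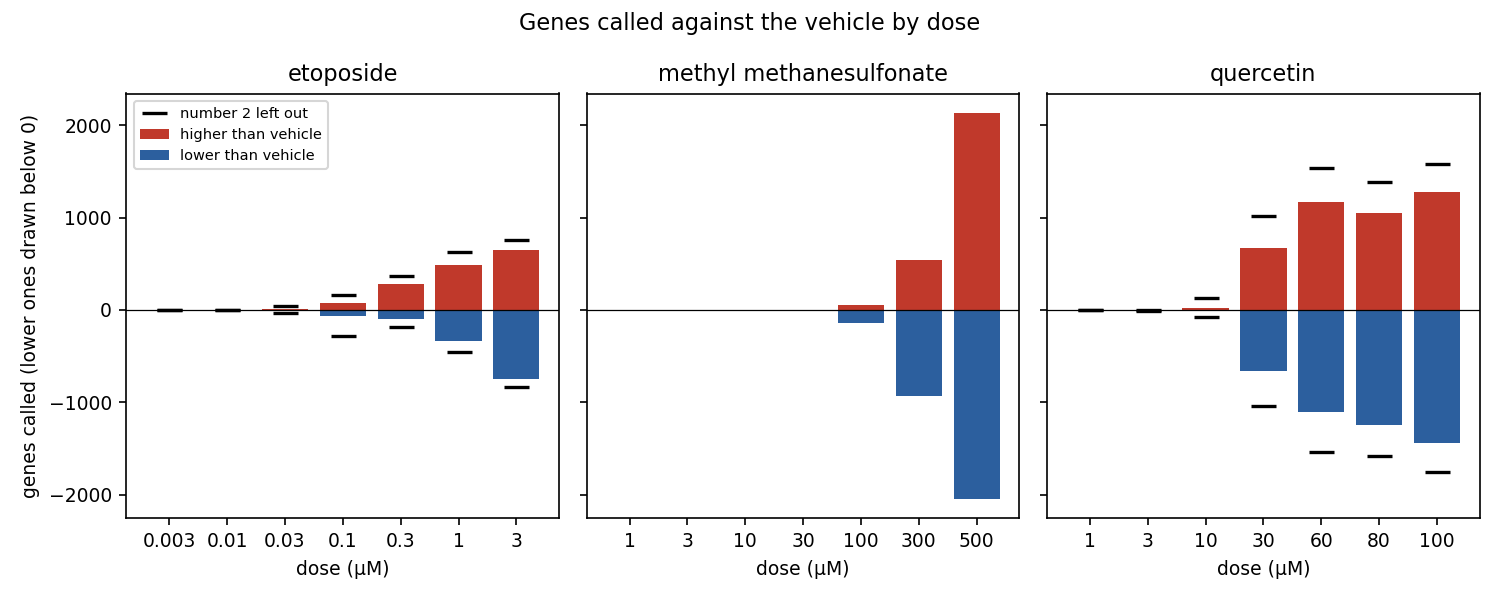
Genes called higher (up) and lower (down) than the own vehicle at each dose in µM, with dashes for the counts without number 2 in the ETP and QUE experiments. Counts rose from 0 at the lowest doses to 1399 at ETP 3 µM, 4173 at MMS 500 µM and 2713 at QUE 100 µM.

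Several of these counts rested on single arrays. Without number 2 in every ETP and QUE group, ETP changed 76 genes at 0.03 µM and 451 at 0.1 µM, and QUE changed 4 at 1 µM, 11 at 3 µM, 215 at 10 µM and 2057 at 30 µM. At ETP 0.03 µM the count of 14 was 8 without vehicle number 1, vehicle number 6 or dosed number 5, 7 without dosed number 6 and 22 without dosed number 2. The 136 genes at ETP 0.1 µM became 232 without dosed number 2, and the 1323 at QUE 30 µM became 1994. At QUE 10 µM, 24 genes became 11, 15, 15, 4 or 5 without vehicle number 1, 2, 4, 5 or 6. Without dosed number 2, 3, 4, 5 or 6 they became 73, 9, 8, 6 or 9.

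CDKN1A, the inhibitor of cyclin-dependent kinases that p53 activates, and MDM2, the ubiquitin ligase that restrains p53, were called first at ETP 0.03 µM, MMS 100 µM and QUE 30 µM, also with the block. CDKN1A rose by 0.61 ± 0.12 (log2, SE) at ETP 0.03 µM and by 1.72 ± 0.12 at 3 µM, by 0.69 ± 0.10 at MMS 100 µM and 1.41 ± 0.10 at 500 µM, and by 0.75 ± 0.18 at QUE 30 µM and 1.40 ± 0.18 at 100 µM. For MDM2 the changes at the highest doses were 1.33 ± 0.12, 0.89 ± 0.13 and 1.14 ± 0.10. GDF15, a secreted factor of the TGF-beta family, was called first at ETP 0.1 µM, MMS 300 µM and QUE 30 µM. With the block GDF15 was also called at QUE 10 µM (0.70 ± 0.15, adjusted p = 0.0051), and at ETP 0.03 µM (0.54, adjusted p = 9.2e-06) and MMS 100 µM (0.32, adjusted p = 1.0e-04) it passed under 1.5-fold. HMOX1, heme oxygenase 1, rose by 3.88 ± 0.21 at MMS 500 µM alone among the MMS doses, and from QUE 30 µM on (from 10 µM on with the block, adjusted p = 3.6e-04), by 2.17 ± 0.48 at 100 µM. At ETP 3 µM its change was 0.78 ± 0.43 and did not pass the test (adjusted p = 0.166, and 3.9e-04 with the block). Without number 2 it was 0.50 ± 0.35 (adjusted p = 0.255). With the block HMOX1 was also called at ETP 1 µM (0.65, adjusted p = 0.0033), and without number 2 it stood there at 0.40 (adjusted p = 0.404). CYP1A1, the cytochrome P450 induced by the aryl hydrocarbon receptor, rose by 1.27 ± 0.15 at MMS 300 µM, 2.26 ± 0.15 at MMS 500 µM and 0.86 ± 0.16 at ETP 3 µM. Its vehicle means lay under 4, so the sizes of these rises are uncertain, and at QUE 100 µM both means did, so no change is given. Without number 2, CYP1A1 was also called at ETP 1 µM (0.61 ± 0.13), and HMOX1 (1.90 ± 0.39) and GDF15 (0.75 ± 0.18) were called at QUE 10 µM.

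**Figure D3:**
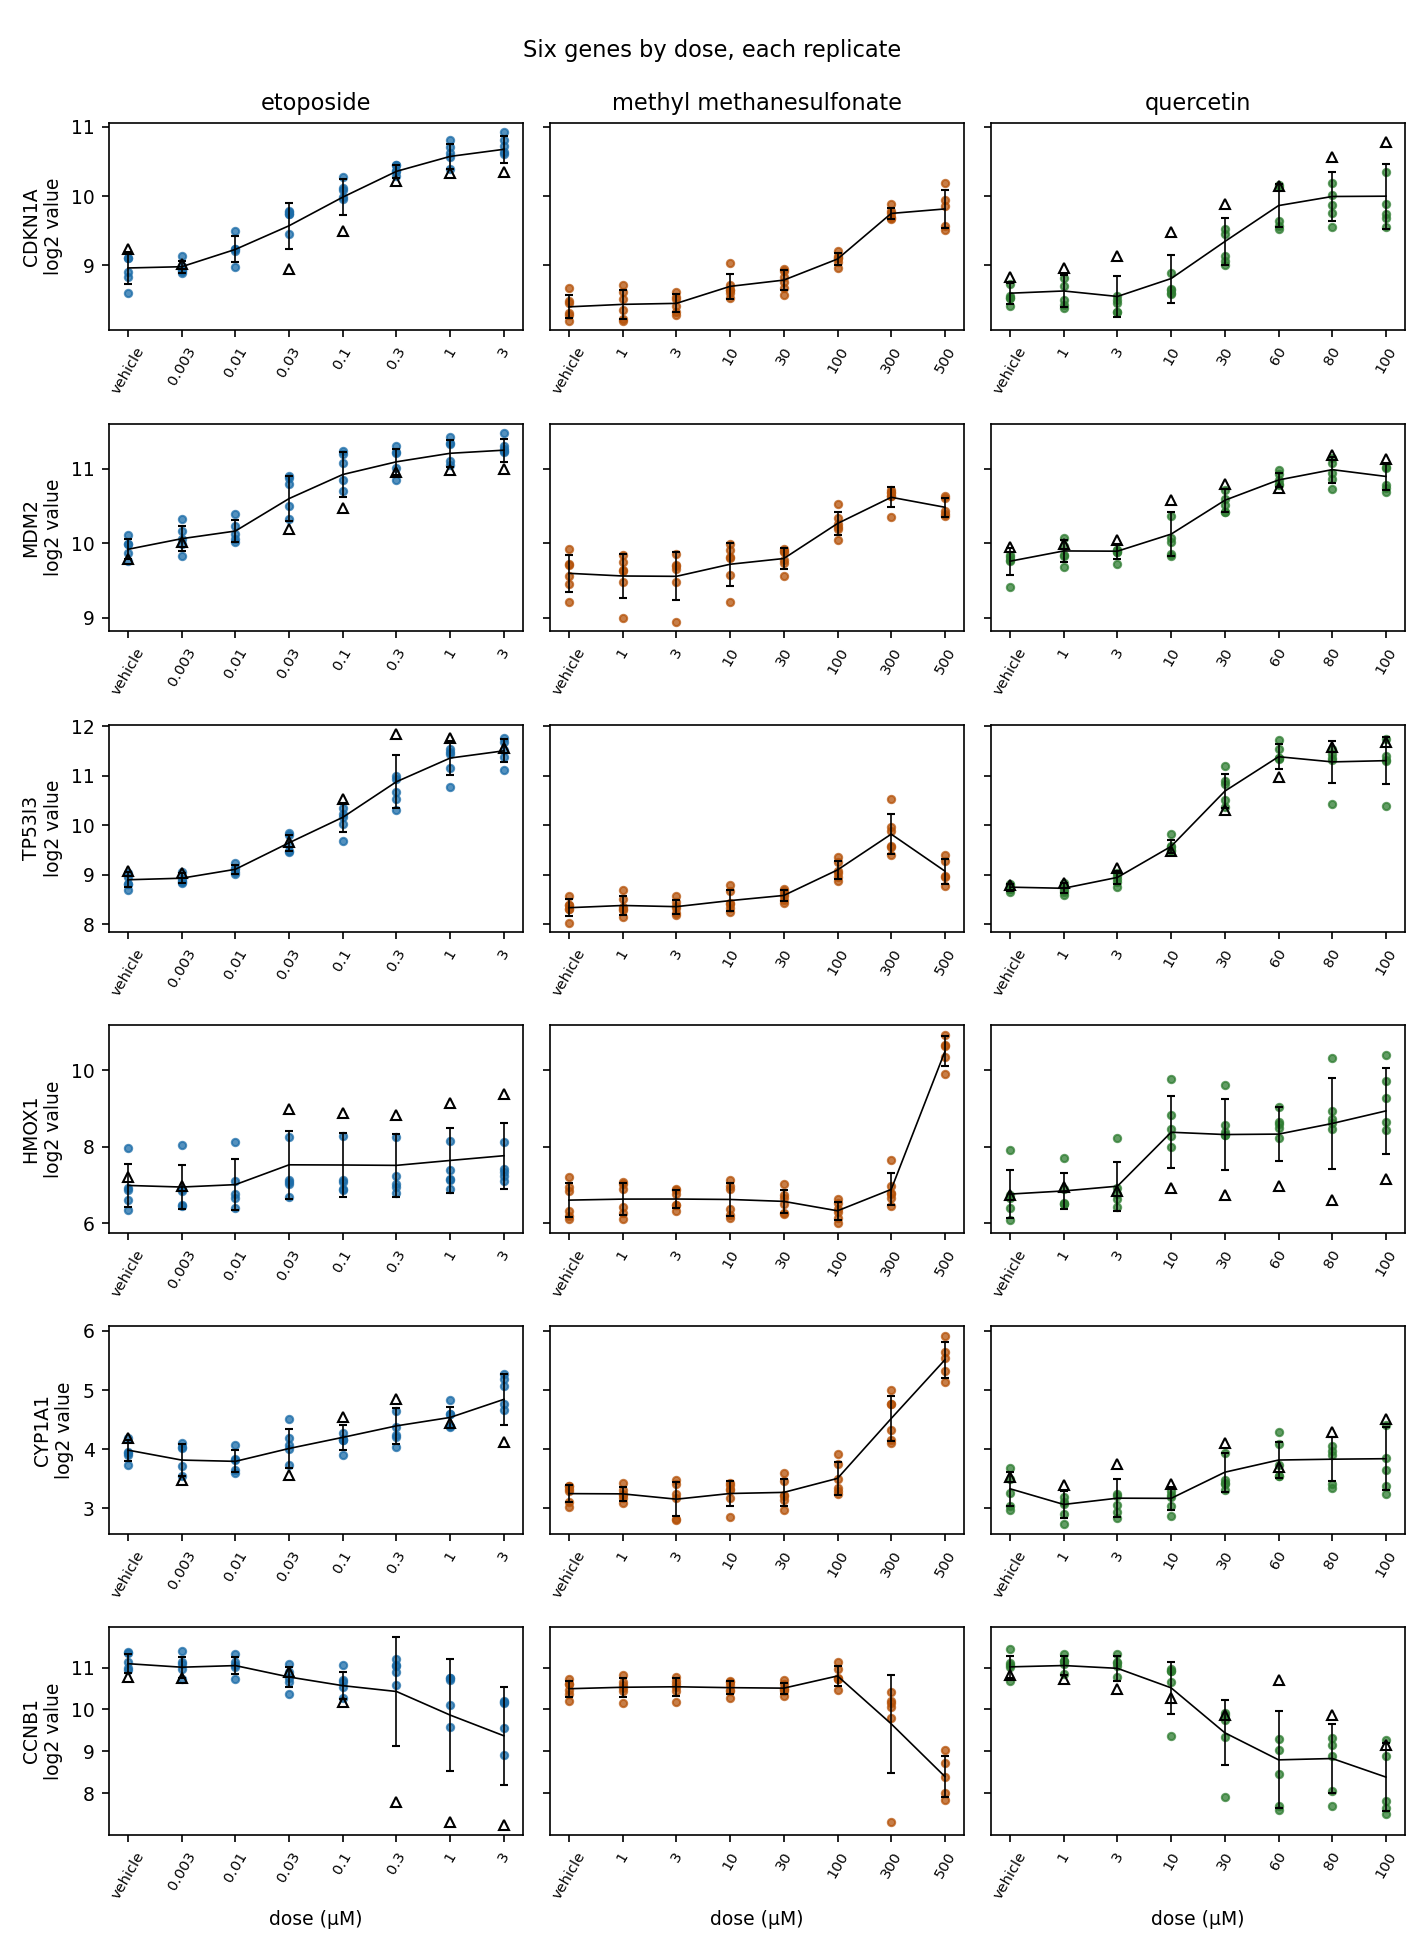
Log2 values of CDKN1A, MDM2, TP53I3, HMOX1, CYP1A1 and CCNB1 against dose in µM, with the vehicle first and the doses equally spaced. Points stand for replicates, triangles for number 2 of ETP and QUE, and lines for the mean with its SD. CDKN1A lay 1.72, 1.41 and 1.40 above its vehicle at the highest doses of ETP, MMS and QUE.

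The comparison of ETP 3 µM with its vehicle (n = 6 and 6) asked which genes the topoisomerase II poison moves. It raised 649 genes and lowered 750 (712 and 683 with quantile normalization over all arrays). The largest measured rise was that of TREM2, a receptor of myeloid cells, at 8.13 ± 0.51 (log2, SD) against 3.37 ± 0.21. The rise of 4.76 ± 0.25 (SE), with an adjusted p of 1.81e-18, is uncertain in size, since the vehicle mean lay under the filter level of 4. AKR1B10, an aldo-keto reductase, stood at 8.11 ± 0.74 against 4.23 ± 0.29 and rose by 3.88 ± 0.30. NECTIN4, a cell adhesion molecule, rose by 3.45, SULF2, a sulfatase of heparan sulfate, by 3.11, CSTA, a cysteine protease inhibitor, by 3.04, CCDC148 by 3.00, ATF3, a stress-induced transcription factor, by 2.99 and NBEAP1 by 2.95. The vehicle means of SULF2, CSTA, CCDC148 and NBEAP1 also lay under 4. Among genes whose dosed and vehicle arrays did not overlap, the largest falls were those of KIF15, a mitotic kinesin, at 5.32 ± 0.47 against 7.45 ± 0.27, HJURP, the chaperone of centromeric histone, LMNB1, the nuclear lamin B1, PSRC1, SPC25, MCM6, a subunit of the replicative helicase, POLA1, the DNA polymerase alpha subunit, and CENPA. These fell by 2.06 to 2.14 on the log2 scale, and all 6 dosed arrays of each of the 16 genes lay beyond all 6 vehicle arrays. With both number 2 and the limit on overlap left out, the largest falls were those of FAM111B (-2.54), ZNF367 (-2.38), MCM6 (-2.37) and SLC1A4 (-2.24), ahead of KIF15 (-2.15).

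Of 32 measured p53-activated targets, 28 rose at ETP 3 µM and 0 fell, also 28 when adjusted over the list alone. Their median change was 1.15 (camera adjusted p = 1.1e-33, and 7.4e-05 with an estimated correlation). ACER2, a ceramidase, rose by 2.65, TP53I3 by 2.60 ± 0.16 (11.50 ± 0.23 against 8.90 ± 0.15), TP53INP1 by 2.58 ± 0.14 and SPATA18 by 2.01. The G2/M and mitosis list fell, with 25 of 28 genes lower and 0 higher (26 adjusted over the list alone), a median of -1.57 and an adjusted p of 1.6e-12. With an estimated correlation its adjusted p was 0.52. The mean value of this list at ETP 3 µM was 6.54 in number 2, against 7.68 to 8.84 in the other arrays. The fall in all arrays is thus in part that of number 2. BUB1B, a spindle checkpoint kinase, fell by 2.01 on the log2 scale, AURKB by 1.98 and DLGAP5 by 1.91. With number 2 left out of every group BUB1B stood at -1.69 and AURKB at -1.84. Without dosed number 2 alone DLGAP5 stood at -1.31 and was no longer called (adjusted p = 0.074), and without number 2 in every group it stood at -1.38 and was called (adjusted p = 8.9e-08). For G1/S and DNA replication 15 of 29 fell and 1 rose (16 and 1 adjusted over the list alone), with an adjusted p of 8.2e-08, and 0.61 with an estimated correlation. GINS2 fell by 1.80 and MCM3 by 1.62 on the log2 scale. In homologous recombination and Fanconi anemia 9 of 15 fell and 0 rose (10 adjusted over the list alone), with an adjusted p of 0.00055, and 0.71 with an estimated correlation. BRIP1 fell by 1.54, BARD1 by 1.36, RAD54L by 0.97 and BLM by 0.95 on the log2 scale.

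Histone probe sets rose in 7 of 17 cases and fell in 2 at ETP 3 µM (9 and 2 adjusted over the list alone), with an adjusted p of 0.0084, and 0.68 with an estimated correlation. H2BC4 rose by 1.52, H2BC5 by 1.14 and H2AC6 by 1.11, and H4C3 fell by 0.97 on the log2 scale, with the family member uncertain. Among 20 apoptosis regulators 7 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.0093, and 0.028 with an estimated correlation). FAS, a death receptor also listed among the p53-activated targets, rose by 1.90, BIK by 1.16 and BAK1 by 0.87. BCL2, which opposes cell death, fell by 1.01 on the log2 scale. Without any one of vehicle or dosed numbers 1, 3, 4, 5 and 6 the adjusted p of BCL2 was 0.057 to 0.089. Without number 2 in every group BCL2 stood at -1.38 (adjusted p = 1.5e-11), and in the mean of its probe sets at -0.53, under 1.5-fold. Its adjusted p was 0.062 with no filter and 0.054 with quantile normalization over all arrays. Of 17 interferon-stimulated genes 6 rose and 0 fell, also when adjusted over the list alone, with an adjusted p of 0.025, and 0.68 with an estimated correlation. ISG15 rose by 1.17, IFI6 by 1.09, OAS2 by 0.88 and IFIT3 by 0.80. NF-kB and secreted inflammatory factors did not pass as a list (4 of 16 higher, adjusted p = 0.38), and TNFAIP3 rose by 1.11 and RELB by 1.06. NEIL3, a DNA glycosylase, fell by 1.80 and UNG, uracil-DNA glycosylase, by 0.95 on the log2 scale, with 1 of 20 base excision and direct repair genes higher and 2 lower (adjusted p = 0.24).

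The remaining lists did not pass at ETP 3 µM. The ATF4 integrated stress response had 2 of 22 genes higher and 2 lower (2 and 1 adjusted over the list alone), with PHGDH, an enzyme of serine synthesis, at -1.36 and SLC7A11, the cystine transporter, at -1.40. Without any one of vehicle numbers 2 to 6 or dosed numbers 1, 4, 5 and 6 the adjusted p of SLC7A11 was 0.051 to 0.12. In the mean of its probe sets SLC7A11 stood at -1.03 and was not called (adjusted p = 0.13), and 0 of its 2 other kept probe sets were called. Higher and lower genes numbered 1 and 0 of 18 endoplasmic reticulum chaperones (DNAJB9 0.90), 1 and 0 of 14 heat shock proteins (HSPB8 0.80) and 1 and 1 of 21 NRF2 antioxidant genes, whose median of -0.01 and mean of 0.17 differed in sign. They were 1 and 0 of 7 aryl hydrocarbon receptor targets, 0 and 1 of 24 hypoxia and HIF targets (HK2 -0.73), 0 and 2 of 18 cholesterol and fatty acid synthesis genes (SREBF1 -0.73, ACACA -0.69), and 0 and 0 of 5 metallothioneins. Immediate early genes had 1 of 14 higher (JUNB 0.68), extracellular matrix and TGF-beta targets 2 of 23 higher (ACTA2 1.68, MMP3 0.96), ribosome biogenesis 1 of 21 lower (UTP20 -0.99) and housekeeping controls 0 of 11. Without number 2, ETP 3 µM changed 1589 genes (754 higher, 835 lower), of which 1204 were among the 1399 and moved the same way. The p53 list then had 27 genes higher, SLC7A11 stood at -1.93, and TDG (0.55) and SREBF1 (-0.56) were no longer 1.5-fold. TDG, at 0.65 in all arrays, was also under 1.5-fold without dosed number 1 (0.57), as were HK2 (-0.44) and ACACA (-0.37) in the mean of their probe sets.

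Lower doses of ETP were described in the same way, and no test compared doses. At 0.03 µM the p53-activated targets already rose, with 9 of 32 higher (10 adjusted over the list alone), a median of 0.46 and an adjusted p of 3.5e-51, and 4.4e-06 with an estimated correlation. The largest rises there were those of TP53INP1 (1.00 ± 0.14, adjusted p = 1.2e-04), SUGCT (0.95) and SPATA18 (0.91; adjusted p = 0.063 without vehicle number 6 and 0.052 without dosed number 6), and LOC105376944 fell by 0.84 on the log2 scale. Without any one of vehicle or dosed numbers 1, 3, 4, 5 and 6 its adjusted p was 0.053 to 0.25. At 0.1 µM NECTIN4 rose by 1.84, CDH10 by 1.62 and TREM2 by 1.61, and E2F8, a repressor of the E2F family, fell by 1.37 and CDCA7 by 1.23 on the log2 scale. At 0.3 and 1 µM TREM2 rose by 3.78 and 4.73, AKR1B10 by 2.45 and 3.35 and NECTIN4 by 2.67 and 3.28, and MCM6 fell by 1.82 and 2.06 and FAM111B by 1.88 and 2.05 on the log2 scale. Without number 2, MCM6 stood at -2.16 and -2.45 and FAM111B at -2.70 and -2.83 at these doses. At 0.1 µM 10 of 29 G1/S and DNA replication genes fell and 0 rose (16 adjusted over the list alone), with an adjusted p of 1.1e-16, and 0.30 with an estimated correlation. Without number 2 these counts were 21 and 22.

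MMS 500 µM against its vehicle (n = 5 and 6) asked which genes the alkylating agent moves. It raised 2133 genes and lowered 2040. HSPA6, an inducible heat shock protein, stood at 9.82 ± 2.56 (log2, SD) against 3.46 ± 0.24 and rose by 6.37 ± 0.48 (SE), with an adjusted p of 2.79e-15. MYCT1 rose by 6.19 ± 0.27. AKR1C1, an aldo-keto reductase under NRF2, stood at 10.94 ± 0.26 against 5.51 ± 0.31 and rose by 5.42 ± 0.20 (adjusted p = 8.09e-26), with the family member uncertain. MMP3, a matrix metalloproteinase, rose by 4.81, SPANXC by 4.55, NMRAL2P by 4.16, IL13RA2, a receptor of interleukin 13, by 4.02 and BMP2, a bone morphogenetic protein, by 3.97. DPYD, the enzyme that degrades pyrimidines, fell by 5.82 on the log2 scale, from 8.88 ± 0.10 to 3.06 ± 0.21 (adjusted p = 2.16e-22). TENM2 fell by 5.77, COL13A1, a transmembrane collagen, by 5.25, PTGES, prostaglandin E synthase, by 5.20 and VCAN, the proteoglycan versican, by 5.07 on the log2 scale. GPC6, a glypican, stood at -5.02, PLAT, tissue plasminogen activator, at -4.95 and LRRC17 at -4.86. For these 16 genes all 5 dosed arrays lay beyond all 6 vehicle arrays. The vehicle means of HSPA6, MYCT1, MMP3, NMRAL2P and IL13RA2 and the dosed means of DPYD, TENM2, PTGES and LRRC17 lay under 4, so the sizes of their changes are uncertain.

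All 28 measured G2/M and mitosis genes fell at MMS 500 µM, also when adjusted over the list alone, with a median of -1.74 and an adjusted p of 1.5e-10, and 0.59 with an estimated correlation. KIF20A fell by 3.20, DLGAP5 by 3.11, CENPA by 2.82 and TOP2A, the topoisomerase II alpha gene, by 2.51 on the log2 scale. NRF2 antioxidant genes rose, with 14 of 21 higher and 0 lower, also when adjusted over the list alone, and an adjusted p of 1.2e-07, and 0.0098 with an estimated correlation. SLC7A11 rose by 2.95 (11.32 ± 0.15 against 8.37 ± 0.40), AKR1C2 by 3.26, HMOX1 by 3.88 and NQO1, a quinone reductase, by 1.42. Of 14 heat shock proteins 7 rose and 0 fell, also when adjusted over the list alone (adjusted p = 0.0015, and 0.59 with an estimated correlation). HSPA1A rose by 2.46, HSPA1L by 1.56, HSPB8 by 1.23 and DNAJB1 by 1.16, with the HSPA1 member uncertain. Of 32 p53-activated targets 18 rose and 1 fell, also when adjusted over the list alone, with a median of 0.72 and an adjusted p of 0.0004, and 0.30 with an estimated correlation. PLK3 rose by 1.49, TP53INP1 by 1.38 and FAS by 1.32.

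Hypoxia and HIF targets fell at MMS 500 µM, with 18 of 24 lower and 1 higher (19 and 1 adjusted over the list alone) and an adjusted p of 2.5e-08, and 0.31 with an estimated correlation. CA12, a carbonic anhydrase, fell by 3.19, ALDOC by 3.04, VEGFA, the endothelial growth factor, by 1.92 and PDK1 by 1.81 on the log2 scale. In cholesterol and fatty acid synthesis 13 of 18 fell and 0 rose, also when adjusted over the list alone (adjusted p = 2.6e-05, and 0.51 with an estimated correlation). SCD, the stearoyl-CoA desaturase, fell by 3.03, STARD4 by 2.29, INSIG1 by 1.92 and MSMO1 by 1.56 on the log2 scale. Extracellular matrix and TGF-beta targets fell in 15 of 23 cases and rose in 1, also when adjusted over the list alone, with an adjusted p of 0.0018, and 0.51 with an estimated correlation. THBS1, thrombospondin, fell by 4.20, COL1A1, type I collagen, by 3.42 and LOX, lysyl oxidase, by 2.82 on the log2 scale. Ribosome biogenesis rose in 8 of 21 cases and fell in 0, also when adjusted over the list alone (adjusted p = 0.038, and 0.89 with an estimated correlation). BYSL rose by 1.38, NOP2 by 1.11 and RRP12 by 1.09. Housekeeping controls passed with 2 of 11 lower and 1 higher, a median of -0.20 and an adjusted p of 0.032, and 0.41 with an estimated correlation. HPRT1 fell by 1.02 and PGK1 by 0.83 on the log2 scale, and TBP rose by 0.61. TBP was under 1.5-fold without vehicle number 2 (0.58) or dosed number 4 (0.54), with quantile normalization over all arrays (0.58) and with the replicate block (0.57).

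The other lists did not pass at MMS 500 µM. Higher and lower genes numbered 2 and 11 of 29 for G1/S and DNA replication (adjusted p = 0.068; POLA1 -2.22, TK1 -1.67), 0 and 5 of 17 histone genes (H2BC4 -0.98) and 2 and 2 of 15 in homologous recombination and Fanconi anemia (FANCG -0.85, PALB2 0.71). Base excision and direct repair had 3 and 3 of 20, with a median and a mean of opposite sign near 0. Within it MGMT, which removes alkyl groups from guanine, fell by 1.18 on the log2 scale, and ALKBH2, another enzyme of direct repair, rose by 0.88. Apoptosis regulators had 5 and 1 of 20 (XIAP 0.83, BCL2L1 0.78), and the ATF4 integrated stress response 8 and 2 of 22, with ATF3 at 3.48 and DDIT4 at -2.88. Endoplasmic reticulum chaperones had 1 and 3 of 18 (PDIA4 -1.04), aryl hydrocarbon receptor targets 2 and 1 of 7 (AHRR -1.19) and metallothioneins 0 and 0 of 5. For NF-kB and secreted inflammatory factors the counts were 7 and 2 of 16 (IL24 2.22 ± 0.78, IL1B -1.75, CXCL3 1.64), for interferon-stimulated genes 3 and 5 of 17 (OAS1 -2.58, IFITM1 -1.72) and for immediate early genes 5 and 1 of 14 (EGR1 2.11 ± 0.81). Without dosed number 5, IL24 stood at 1.52 (adjusted p = 0.094) and EGR1 at 1.54 (adjusted p = 0.11), and the adjusted p of EGR1 was 0.060 and 0.053 without vehicle number 2 or 3.

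AKR1C1 and SPANXC led the rises at lower doses of MMS, by 2.32 ± 0.19 and 1.79 ± 0.18 at 100 µM and by 4.69 and 3.82 at 300 µM. NECTIN4 rose by 1.68 and 3.06. LRRC17 fell by 1.70 at 100 µM and 4.10 at 300 µM on the log2 scale, RPS6KA2, a ribosomal S6 kinase, by 1.48 and 3.19, ITGB8, an integrin, by 1.62 at 100 µM and TENM4 by 3.35 at 300 µM. The p53-activated targets rose in 12 of 32 cases at 100 µM and in 20 at 300 µM (12 and 21 adjusted over the list alone), with adjusted p of 4.8e-27 and 1.1e-16, and 1.4e-05 and 0.00048 with an estimated correlation.

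QUE 100 µM against its vehicle (n = 6 and 6) asked which genes the flavonol moves. It raised 1277 genes and lowered 1436. TREM2 stood at 6.60 ± 1.38 (log2, SD) against 2.83 ± 0.12 and rose by 3.76 ± 0.43 (SE), with an adjusted p of 9.14e-09. Dosed number 3 stood at 3.90, against 6.70 to 7.90 in the other dosed arrays, and the SE and p use 1 spread over all 8 QUE groups. CYP4F2 and CYP4F3, which hydroxylate fatty acids, rose by 3.65 ± 0.47 and 3.64 ± 0.60. LCE1B, a protein of the cornified envelope, rose by 3.45, ATF3 by 3.03 (8.52 ± 0.22 against 5.48 ± 0.41), KLF5, a transcription factor, by 3.01, FEZ1 by 2.74 and ACER2 by 2.66. DLGAP5, a spindle protein, fell by 3.76 on the log2 scale, from 9.55 ± 0.17 to 5.79 ± 1.45 (adjusted p = 6.69e-06). The checkpoint kinases BUB1B and BUB1 fell by 3.10 and 2.95, ASPM, a spindle pole protein, by 3.00, TENM4 by 2.92, PDE5A, a phosphodiesterase of cyclic GMP, by 2.87, HMMR by 2.87 and KIF20A by 2.85 on the log2 scale. All 6 dosed arrays of these 16 genes lay beyond all 6 vehicle arrays. The vehicle means of TREM2, CYP4F2, CYP4F3, LCE1B, FEZ1 and ACER2 lay under 4, so the sizes of their rises are uncertain. With both number 2 and the limit on overlap left out, the largest falls were those of GALNT15 (-4.18), DLGAP5 (-4.17), SLC2A12 (-3.81), TGFB2 (-3.81), GNG2 (-3.78) and PDE7B (-3.77), and CYP4F3 (4.11) led the rises.

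Of 32 p53-activated targets 29 rose at QUE 100 µM and 0 fell, also when adjusted over the list alone, with a median of 1.23 and an adjusted p of 2e-25, and 4.6e-05 with an estimated correlation. TP53I3 rose by 2.55, FAS by 2.30 and SPATA18 by 2.24. All 28 G2/M and mitosis genes fell, also when adjusted over the list alone, with a median of -2.09 and an adjusted p of 1.1e-17, and 0.32 with an estimated correlation. In G1/S and DNA replication 11 of 29 fell and 0 rose, also when adjusted over the list alone (adjusted p = 0.0046, and 0.93 with an estimated correlation). POLE2 fell by 2.00, POLA1 by 1.55 and MCM6 by 1.42 on the log2 scale. Endoplasmic reticulum chaperones rose in 4 of 18 cases and fell in 0, also when adjusted over the list alone (adjusted p = 0.00053, and 0.57 with an estimated correlation). DNAJB9, an endoplasmic reticulum cochaperone, rose by 1.48 and HYOU1 by 0.65. The ATF4 integrated stress response had 8 of 22 higher and 0 lower (7 adjusted over the list alone), with an adjusted p of 0.034, and 0.93 with an estimated correlation. PPP1R15A, which restores translation after stress, rose by 1.96, SESN2 by 1.57 and NUPR1 by 1.44.

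Heat shock proteins fell at QUE 100 µM, with 4 of 14 lower and 0 higher, also when adjusted over the list alone, and an adjusted p of 0.0061, and 0.68 with an estimated correlation. HSPA4L fell by 1.31, HSPA1A by 0.96 and DNAJA1 by 0.83 on the log2 scale. Without vehicle number 1 or dosed number 1, 4, 5 or 6 the adjusted p of HSPA4L was 0.054 to 0.071, and without dosed number 3 or 4 that of HSPA1A was 0.060 and 0.058. NF-kB and secreted inflammatory factors rose in 5 of 16 cases and fell in 0, also when adjusted over the list alone (adjusted p = 0.012, and 0.52 with an estimated correlation). TNFAIP3, a brake on NF-kB, rose by 1.84 and RELB by 1.56. Immediate early genes rose in 5 of 14 cases and fell in 1 (6 and 1 adjusted over the list alone), with an adjusted p of 0.033, and 0.51 with an estimated correlation. EGR1 rose by 1.65 and FOS by 1.38, and PHLDA1 fell by 1.49 on the log2 scale, but by 0.22 in the mean of its probe sets, which did not pass. Cholesterol and fatty acid synthesis fell in 8 of 18 cases and rose in 1, also when adjusted over the list alone (adjusted p = 0.022, and 0.84 with an estimated correlation). HMGCS1 fell by 1.05, DHCR7 by 1.03 and FDPS by 0.92 on the log2 scale. Apoptosis regulators rose in 6 of 20 cases and fell in 1, also when adjusted over the list alone (adjusted p = 0.030, 0.22 with an estimated correlation and 0.066 without number 2), with BCL2L1 at 0.99 and BAK1 at 0.89.

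The other lists did not pass at QUE 100 µM. Higher and lower genes numbered 3 and 2 of 17 histone genes (H2AC8 1.06, H4C3 -0.84), 0 and 4 of 15 in homologous recombination and Fanconi anemia (FANCB -0.87), and 2 and 3 of 20 in base excision and direct repair (NEIL3 -2.02, TDG 0.72). NRF2 antioxidant genes had 2 and 0 of 21, with AKR1B10 at 2.50 beside HMOX1. Aryl hydrocarbon receptor targets had 0 and 1 of 7 (AHRR -0.92; -0.82 and adjusted p = 0.051 without dosed number 4), with a median of -0.12 against a test in the other direction (adjusted p = 0.94). Hypoxia and HIF targets had 3 and 4 of 24 (PDK1 -0.94, INSIG2 0.70), metallothioneins 0 and 0 of 5, interferon-stimulated genes 2 and 5 of 17 (IFIT1 -1.45, RIGI -1.16), extracellular matrix and TGF-beta targets 2 and 3 of 23 (ACTA2 2.00, TGFBI -1.94), ribosome biogenesis 0 and 2 of 21 (UTP20 -1.51) and housekeeping controls 0 and 1 of 11 (HPRT1 -0.73). Without number 2, QUE 100 µM changed 3332 genes (1581 higher, 1751 lower), of which 2644 were among the 2713 and moved the same way. The ATF4 list then had 11 genes higher and 1 lower (camera adjusted p = 0.00072) and the NF-kB list 8 and 0 (adjusted p = 0.0019), both with the preset correlation. In all arrays neither list passed with an estimated correlation. KLF5 rose by 3.32 ± 0.15 and CYP4F3 by 4.11 ± 0.26 without number 2. With the arrays left out that have a suffix in their title, HSPA4L (adjusted p = 0.118), HMGCS1 (0.0545), AHRR (0.110) and KRT15 (0.0646) were no longer called, and HYOU1 (0.51) was under 1.5-fold.

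At lower doses of QUE, AKR1C1 rose by 2.57 ± 0.55 at 10 µM, NMRAL2P by 2.56 and AKR1C2 by 1.63, and PHF2P1 fell by 0.89 on the log2 scale. Without vehicle number 1, 5 or 6 or dosed number 3, 4, 5 or 6 the adjusted p was 0.057 to 0.095 for AKR1C1 and 0.061 to 0.098 for AKR1C2. For NMRAL2P it was 0.050 to 0.12 without any one array except dosed number 2, and for PHF2P1 it was 0.051 without vehicle number 5. Without number 2 in every group all 4 were called, AKR1C1 at 3.19 (adjusted p = 3.9e-06), NMRAL2P at 3.08 (8.3e-05), AKR1C2 at 1.97 (3.0e-04) and PHF2P1 at -1.07 (4.9e-06). Of 21 NRF2 antioxidant genes 3 rose at 10 µM (9 adjusted over the list alone), with a median of 0.54 and an adjusted p of 5e-20, and 0.0013 with an estimated correlation. Without number 2 the count was 11. At 30 µM HSD17B2, a steroid dehydrogenase, rose by 2.94, ESM1 by 2.68 and KLF5 by 2.56, and GALNT15 fell by 3.08, DLGAP5 by 2.69 and RAB26 by 2.49 on the log2 scale. The calls of ESM1 and RAB26 ended without number 3 in every group (adjusted p = 0.0521 and 0.0725), and that of RAB26 without dosed number 1 (0.060) or 3 (0.056). At 60 and 80 µM TREM2 rose by 4.11 and 3.86, CYP4F3 by 3.67 and 3.36 and CYP4F2 by 3.44 and 3.32, and GALNT15 fell by 3.49 and 3.08 and SLC2A12, a glucose transporter, by 3.22 and 3.03 on the log2 scale. At 30 µM 23 of 32 p53-activated targets rose and 23 of 28 G2/M and mitosis genes fell, both also when adjusted over the list alone. Their adjusted p were 1.3e-24 and 1.3e-11, and 5.7e-05 and 0.51 with an estimated correlation.

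**Figure D4:**
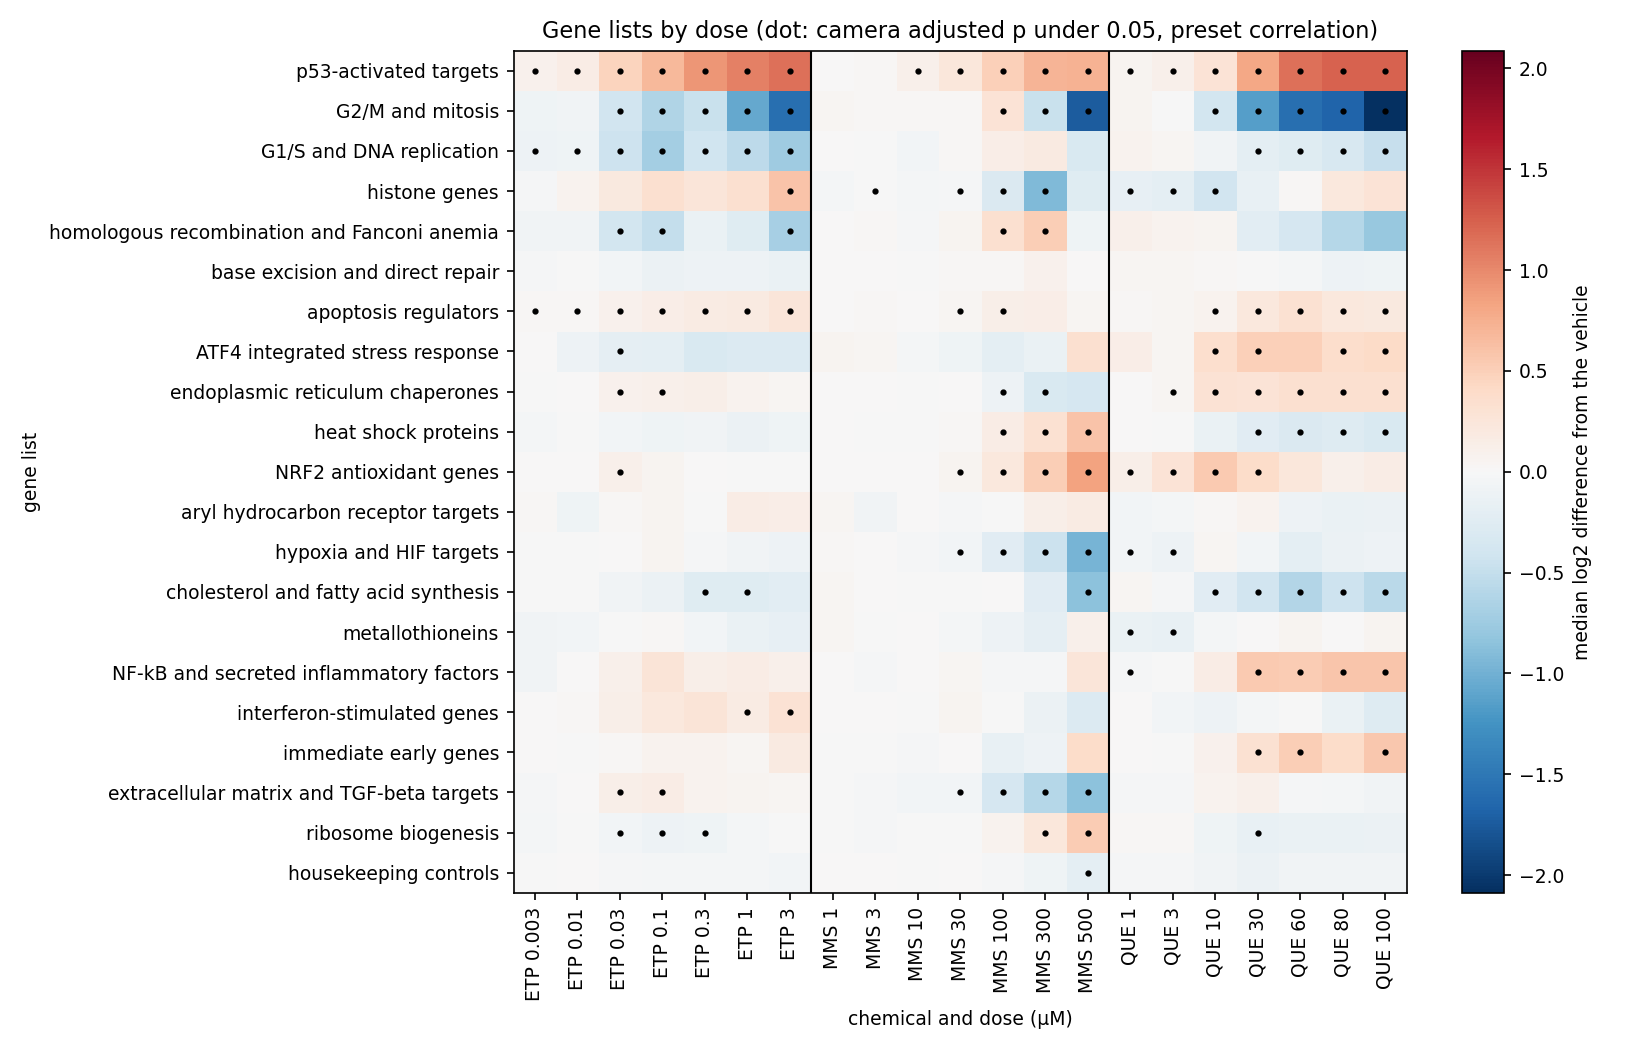
Median log2 change of 21 gene lists (vertical) at the 7 doses of each chemical in µM (horizontal), with dots where the camera adjusted p was under 0.05. All arrays are used as labelled, number 2 included. The p53-activated targets stood at 1.15, 0.72 and 1.23 at the highest doses of ETP, MMS and QUE, and the G2/M and mitosis list at -1.57, -1.74 and -2.09.

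Markers of other cell types could hardly be read. Of the epithelial markers 1 of 13 was measured, KRT15, at -2.20 at MMS 500 µM and -1.61 at QUE 100 µM. Of the blood cell markers 3 of 14 were measured, and LAPTM5 rose by 2.45 at ETP 3 µM and 1.55 at QUE 100 µM. Neither list was tested. Of the named called genes with other kept probe sets, 18 of 25 at ETP 3 µM, 42 of 49 at MMS 500 µM and 27 of 35 at QUE 100 µM had another probe set called the same way, and 0 had one called the opposite way.

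The responses to the highest doses were then set against each other, each relative to its own vehicle, at doses that are not matched. Between ETP 3 µM and MMS 500 µM 3048 genes differed (3683 without number 2), 1577 with the ETP change above the MMS change and 1471 below. The largest differences were 5.14 ± 0.49 (log2, SE) for TENM2 (-0.63 and -5.77), 5.08 for VCAN, 5.07 for PLAT, 4.74 for TREM2 and 4.44 for DPYD. In the other direction HSPA6 differed by -5.73, MYCT1 by -4.97, AKR1C1 by -4.72, SLC7A11 by -4.35 and NMRAL2P by -3.86. Between MMS 500 µM and QUE 100 µM 2984 genes differed (3408 without number 2), 1510 above and 1474 below. HSPA6 differed by 5.80, AKR1C1 by 4.24, MYCT1 by 4.00, MMP3 by 3.93 and SPANXC by 3.92. PLAT differed by -4.84, HHIP, an antagonist of hedgehog signalling, by -4.76, COL13A1 by -4.26, TENM2 by -4.22 and GPC6 by -4.18. HMOX1 rose more with MMS than with ETP (difference -3.11, adjusted p = 5.74e-06) or QUE (1.71, adjusted p = 0.0139). CYP1A1 was not ranked, since its vehicle means lay under 4. Differences of genes with a group mean under 4, among them TENM2, TREM2, DPYD, HSPA6, MYCT1, NMRAL2P and MMP3, are uncertain in size, so the order is that of the measured values. For CDKN1A the difference was 0.30 ± 0.20 between ETP and MMS and 0.31 ± 0.20 between ETP and QUE, with adjusted p of 0.25 and 0.35.

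Between ETP 3 µM and QUE 100 µM 1 gene differed, IGFL2, by 1.01 (adjusted p = 1.4e-03), and this count rested on single arrays. It was 1281 with the block and 3527 with array weights, both with all arrays. It was 1604 without ETP 3 µM number 2, 1484 without QUE 100 µM number 2, 2 without QUE 100 µM number 3 and 2828 without number 2 in every ETP and QUE group (1540 above, 1288 below). Without number 2, CDKN1A differed by 0.54 (adjusted p = 4.7e-03), HMOX1 by -2.02 (adjusted p = 2.8e-04), CYP4F3 by -3.54, SLC7A11 by -2.80, FOSL1 by -2.39 and PPP1R15A by -2.17. COL1A1 differed by 3.47 without number 2, HSPA4L by 3.08, TGFBI by 2.83, DLGAP5 by 2.79, H2BC4 by 2.39 and the interferon-stimulated genes IFIT1 and IFI44 by 2.32 and 2.06. These genes, except CDKN1A and HMOX1, were picked after their values were seen.

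Genes called by more than 1 chemical mostly moved the same way. ETP 3 µM and MMS 500 µM shared 279 higher genes (115 by chance) and 515 lower genes (127 by chance), and 39 and 9 moved in opposite ways. ETP 3 µM and QUE 100 µM shared 397 higher (68.7 by chance) and 511 lower (89.2 by chance), and 0 moved in opposite ways. MMS 500 µM and QUE 100 µM shared 652 higher (226 by chance) and 831 lower (243 by chance), and 43 and 35 moved in opposite ways. Chance would give 110 and 133 genes in opposite ways for ETP and MMS, 77.2 and 79.3 for ETP and QUE, and 254 and 216 for MMS and QUE. Shared genes were thus more, and opposite genes fewer, than by chance. In Fisher's exact tests the largest adjusted p of these 12 overlaps was 3.2e-17, for the 39 opposite genes of ETP and MMS. The tests treat genes as independent, which genes that move together are not, so these p-values are too small. Across genes the changes correlated at 0.50 (Spearman 0.50), 0.74 (0.70) and 0.58 (0.54) for the 3 pairs, and genes are not independent replicates. Without number 2 the ETP and QUE overlap was 316 higher and 395 lower, with 52 and 23 in opposite ways, and the correlation was 0.44. The ETP and MMS overlap was then 272 higher and 484 lower, with 84 and 24 in opposite ways, and the correlation was 0.37. For MMS and QUE these were 757 and 921, 74 and 51, and 0.56. All 3 chemicals raised 223 genes (12.1 by chance) and lowered 388 (15.1 by chance), and 176 and 307 without number 2. Of genes picked after their values were seen, ATF3 rose by 3.07, 3.48 and 3.00 for ETP, MMS and QUE without number 2, BMP2 by 2.06, 3.97 and 2.78 and NECTIN4 by 3.87, 1.95 and 2.04. E2F8 fell by 1.96, 2.71 and 2.00, PSRC1 by 1.96, 2.92 and 2.81 and CENPA by 1.86, 2.82 and 2.51 on the log2 scale.

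The vehicle groups of the experiments, which received the same solvent, were compared as a measure of what differs between experiments other than treatment, including their separate normalization. Between ETP and MMS vehicles 6210 genes differed, between ETP and QUE 102 and between MMS and QUE 3439. After quantile normalization over all arrays the counts were 892, 15 and 943.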

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

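The tests of a swap at all doses, of a stronger or weaker dose in number 2 and of a stronger exposure in number 3 were chosen only after the result was seen. The other tests of this part had their predictions written before.

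The first pattern is that arrays labelled number 2 at the 5 highest doses of ETP and QUE responded like the other chemical, 10 of 10 against 0 of the 50 other arrays. A shared effect of number 2 on all its arrays is argued against by the vehicles, whose largest score along the difference between both responses was 0.0443 in size, against 1.18 for the array labelled ETP 3 µM number 2 (0 stands for an ETP response, 1 for a QUE response, over 1165 genes), and a stronger or weaker dose by the 0 of 10 number 2 arrays that correlated best with their own chemical. A swap of the dosed number 2 arrays between both experiments is a candidate explanation that these 10 arrays cannot test, since they are the pattern itself. At the 2 lowest doses, which the pattern leaves out, 3 of 3 number 2 arrays also correlated better with the other chemical, against 0 of 20 others, as a swap of all doses would need, though these values were seen beforehand. Whether whole arrays moved cannot be told apart from an exchange of treatments: over 3130 genes that neither chemical moved, 5 of the 10 followed the number 2 vehicle of the other experiment better than their own, as did 20 of the 50 other arrays, and no biological explanation was tested, since the design gives none.

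The second pattern is that arrays labelled QUE number 3 departed from the other QUE arrays. A batch effect that moved the vehicle along the QUE response is argued against. The slope of the number 3 vehicle on the others' response at 30 µM was 0.0298. This slope cannot exclude a shared effect in another direction. The number 3 vehicle stood highest for HMOX1 (7.92, against 6.09 to 6.74) and for the mean NRF2 antioxidant value (9.20, against 8.82 to 8.91). A rearrangement of doses within number 3 is argued against because 0 of its 3 arrays at 60, 80 and 100 µM matched best a dose under 60 µM. A stronger effective exposure of number 3 is a candidate explanation, since 3 of its 3 arrays at 10, 30 and 60 µM matched best a higher dose, against 0 of the 12 other arrays at these doses. At 80 and 100 µM its correlation with the others' response at the same dose was the lowest, 0.52 and 0.55. Its slopes there were 0.74 and 0.72, so a larger response of the same kind was not seen at these doses. Among all QUE arrays, number 3 at 80 and 100 µM also had the lowest upper quartiles (6.25 and 6.22) and the highest medians (3.41 and 3.41). Whether array or RNA quality differed in number 3 was not tested, since control probe sets were lacking. The labels give no measured exposure, so a stronger exposure stays open, and no biological explanation was tested.

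A test for an array far from the others was run 96 times, each on a gene or a list mean. The arrays were the 5 or 6 of a vehicle or highest-dose group. An array stood apart in 11 tests, where chance gives about 1 in 20 independent tests (4.8 of 96). These tests share arrays and in part use genes picked for large changes, so 4.8 is only a rough guide. Of the 11, 4 were number 2 arrays of ETP or QUE, all among genes with large changes. MDM2 in the QUE vehicle stood at 9.42 (log2) in number 4, against 9.76 to 9.94 in the others. HMOX1 in the QUE vehicle stood at 7.92 in number 3, against 6.09 to 6.74. The mean of the NRF2 antioxidant genes in the QUE vehicle stood at 9.20 in number 3, against 8.82 to 8.91. SULF2 at ETP 3 µM stood at 4.84 in number 2, against 6.30 to 6.97, and CSTA at 5.93 in number 3, against 6.74 to 7.18. HSPA6 at MMS 500 µM stood at 5.41 in number 5, against 10.37 to 12.10. At QUE 100 µM, TREM2 stood at 3.90 in number 3, against 6.70 to 7.90, and FEZ1 at 4.76 in number 3, against 6.65 to 7.60. Also at QUE 100 µM, CYP4F3 stood at 3.82 in number 2, against 6.71 to 7.08, KLF5 at 7.15, against 8.64 to 9.48, and PDE5A at 7.43, against 4.46 to 5.56.

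Kept probe sets without 1 gene symbol, which the comparisons left out, changed as well. Of the 4337, 385 were called at ETP 3 µM (149 higher, 236 lower), or 8.88% against 10.8% of those with 1 symbol. At MMS 500 µM 997 were called (517 higher, 480 lower), or 23.0% against 32.5%. At QUE 100 µM 897 were called (493 higher, 404 lower), or 20.7% against 23.2%.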

How the results depend on the processing

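The settings that leave number 2 out of every ETP and QUE group, or number 3 out of every QUE group, were chosen only after the result was seen. No named gene changed direction under any alternative run, but the balance of higher and lower genes did turn. With quantile normalization over all arrays it was 712 higher and 683 lower at ETP 3 µM and 619 and 698 at QUE 30 µM, and with arrays centred on their median 594 and 746 at QUE 30 µM and 1106 and 1183 at QUE 60 µM. No scaling moved the median of all genes by over 0.1 or the share of higher genes by over 10 points. Suffixed or repeated arrays do not occur for MMS, so those settings gave no values there. The number of arrays and their spread limit precision, and the cause of a change was not tested unless a stricter or looser threshold, or more or fewer genes tested, makes it.

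Without a fold threshold the ETP counts from 0.03 to 3 µM were 25, 403, 1232, 2609 and 3917, and 3121 at any dose. MMS gave 492, 4403 and 7387 from 100 to 500 µM and 7161 at any dose, and QUE gave 2902, 4544, 4586 and 5305 from 30 to 100 µM and 5791 at any dose. Shared higher and lower genes were 1235 and 1201 for ETP and MMS, 1288 and 1229 for ETP and QUE, and 1786 and 1515 for MMS and QUE. Higher genes then made up 41.1% at MMS 100 µM, 53.6% at MMS 300 µM (25.8% and 36.5% at 1.5-fold), 50.9% at ETP 3 µM and at QUE 80 µM and 52.3% at QUE 100 µM. At 2-fold or more, ETP gave 0, 38, 105, 246 and 453 (442 at any dose), MMS 39, 463 and 1814 (1863), and QUE 11, 395, 775, 821 and 1019 from 10 µM on (1139). Differences between chemicals were then 1249 for ETP and MMS and 1283 for MMS and QUE, and shared higher and lower genes 65 and 174, 133 and 182, and 141 and 377 for the same pairs as before. With every probe set tested, ETP gave 23, 233, 737, 1649 and 2835 (2602 at any dose), MMS 305, 2889 and 8397 (8408), QUE 2840, 5088, 5306 and 6169 from 30 µM on (6951), and the differences 5723 for ETP and MMS and 6166 for MMS and QUE.

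Array weights gave 130, 444 and 611 genes at ETP 0.03, 0.1 and 0.3 µM, 31, 45, 338 and 2134 at QUE 1, 3, 10 and 30 µM, 4585 at any QUE dose and 3527 for the difference between ETP and QUE. The replicate block gave 41 and 294 at ETP 0.03 and 0.1 µM, 295 at MMS 100 µM, 2, 3 and 144 at QUE 1, 3 and 10 µM and 1281 for that difference. Without number 2 the counts were 76 and 451 at ETP 0.03 and 0.1 µM, 4, 11, 215 and 2057 at QUE 1, 3, 10 and 30 µM and 2828 for the difference. The share of higher genes at ETP 0.1 µM, 52.9% in all arrays, was 38.1% with array weights, 45.9% with the block and 36.8% without number 2. At MMS 500 µM 37.4% were higher at 2-fold or more, against 51.1%. Without number 3 the share was 51.7% and 52.3% at QUE 80 and 100 µM, against 45.8% and 47.1%. The difference between ETP and QUE was also 0 with a log2 value of at least 6 in 5 arrays, 0 with only the 4 groups compared and 404 with repeats kept separate. QUE 10 µM gave 14 genes without a filter and 86 with only the 2 groups compared. Quantile normalization over all arrays gave 892, 15 and 943 genes between vehicles. With single replicates left out, the counts ranged from 7 to 22 at ETP 0.03 µM, 94 to 232 at ETP 0.1 µM, 4 to 73 at QUE 10 µM, 893 to 1994 at QUE 30 µM and 1 to 1604 for the difference between ETP and QUE. The highest of these came from leaving out a dosed number 2 array, of ETP 3 µM for the difference. All remaining values of the counts stayed within 1.5 times of those of all arrays.

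Of the list tests, 140 of 441 passed with the preset correlation and 29 with an estimated one. At the highest doses 26 lists passed, of which 22 no longer did with the estimated correlation and 1 with fry, which gained 11 others. Leaving out number 2 ended 1 of 17 list calls for ETP and QUE, apoptosis regulators at QUE 100 µM (adjusted p = 0.066). Over the fits that left out 1 replicate, named genes lost a call in 120 cases and gained one in 2, and in 3385 cases a gene stayed called or stayed uncalled. Arrays centred on their median ended 2 calls of named genes, the mean of probe sets 11, no filter 6, quantile normalization over all arrays 4, suffix arrays left out 14, a suffix covariate 1, repeats kept separate 2, the block 1 (with 1 gained), number 2 left out 2 and number 3 left out 8 (with 1 gained).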

Other observations

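The fits without number 2 used in this part were chosen only after the result was seen, and the genes named in it were picked after their values were seen. Several gene lists moved as a whole at doses where few or no genes passed on their own. The p53-activated targets rose from ETP 0.003 µM on (median 0.08, adjusted p = 1.1e-07, and 0.16 with an estimated correlation), from MMS 10 µM on (median 0.11, adjusted p = 5.1e-12, and 0.0042 with an estimated correlation) and from QUE 1 µM on (median 0.05, adjusted p = 0.0035, and 0.48 with an estimated correlation), with 0 of 32 genes called at each of these doses. NRF2 antioxidant genes rose from MMS 30 µM on (adjusted p = 0.0048, and 0.32 with an estimated correlation). With QUE their median was 0.12, 0.28, 0.54 and 0.39 at 1, 3, 10 and 30 µM, with adjusted p of 7.5e-08, 2.4e-28, 5e-20 and 0.0019, and 0.11, 0.00011, 0.0013 and 0.52 with an estimated correlation. At 60, 80 and 100 µM their median was 0.24, 0.11 and 0.16, and the list did not pass (adjusted p = 0.20, 0.34 and 0.35). Without number 2 their median was 0.65 at 10 µM and 0.23 at 100 µM.

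Some lists passed at a middle dose and not at the highest. Histone genes fell at MMS 300 µM, with 10 of 17 lower, also when adjusted over the list alone, a median of -0.91 and an adjusted p of 3e-10, and 0.028 with an estimated correlation. At 500 µM 5 were lower and the list did not pass (adjusted p = 0.18). Homologous recombination and Fanconi anemia rose at MMS 300 µM, with 5 of 15 higher (6 adjusted over the list alone) and an adjusted p of 0.0068, and 0.84 with an estimated correlation. Endoplasmic reticulum chaperones fell at MMS 300 µM in 3 of 18 cases (adjusted p = 1.4e-06, and 0.018 with an estimated correlation). G2/M and mitosis genes had a median of 0.28 at MMS 100 µM (adjusted p = 0.0014, and 0.93 with an estimated correlation), -0.47 at 300 µM and -1.74 at 500 µM. For ETP their median was -0.62 at 0.1 µM, -0.46 at 0.3 µM and -1.06 at 1 µM, and without number 2 it was -0.70, -0.19 and -0.70. The differences between doses were not tested.

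Without number 2, 84 genes were higher at ETP 3 µM and lower at MMS 500 µM. Among them were PLAC8 (1.91 ± 0.17 and -1.63 ± 0.21, log2 with SE), CCDST (2.59 and -1.53) and CD24, a surface glycoprotein (2.40 and -1.49). The 24 lower at ETP and higher at MMS included SLC7A11 (-1.93 ± 0.24 and 2.95 ± 0.21) and CCNE2, cyclin E2 (-1.24 and 0.89). With all arrays, the mean of the SLC7A11 probe sets stood at -1.03 at ETP 3 µM and was not called (adjusted p = 0.13). Of 52 genes higher at ETP 3 µM and lower at QUE 100 µM, GAS6-AS1 stood at 1.53 and -1.95, HSPA4L at 1.13 and -1.96 and COL1A1 at 1.13 and -2.35. Of 23 that moved the other way, CXCL8, the chemokine interleukin 8, stood at -0.81 ± 0.22 and 2.06 ± 0.17, BCL2A1 at -0.81 and 1.91 and FOSL1 at -1.03 and 1.36. RAD50, of the double-strand break repair complex, stood at 1.59 ± 0.13 at MMS 500 µM and -1.38 ± 0.20 at QUE 100 µM, as 1 of 74 such genes. EIF2AK3, the kinase PERK of the unfolded protein response, stood at -1.24 ± 0.14 and 1.71 ± 0.23, as 1 of 51 that moved the other way. A few genes were called in both directions at different doses of a chemical, for ETP and QUE without number 2. NLGN1 stood at 0.61 at ETP 0.1 µM and -0.86 at 3 µM. For MMS they were DGKA, CCDST, NRG1, PLCB4 and MNS1, higher at 300 µM and lower at 500 µM, with DGKA at 1.06 and -0.83. For QUE they were EPHB1 (0.97 at 10 µM, -0.61 at 100 µM), CLMP (0.80 and -0.74) and CSRNP1 (-0.68 and 0.83).

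At QUE 1 and 3 µM, where no gene passed in all arrays, the block called IL1A, interleukin 1 alpha (-1.28 and -1.35), and SCG5 (-1.59 and -1.58) at both doses and SLC37A2 (-0.64) at 3 µM. Without number 2, the 4 genes at 1 µM were CXCL8 (1.11), CFAP251 (-1.26), HPCAL1 (-0.64) and SCG5 (-1.96). Among the 11 at 3 µM were CXCL8 (1.66), AKR1C1 (2.12) and PIR (0.98).

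Other splits of the same arrays were drawn, 100 for each comparison with the real split included. They were drawn without regard to replicate numbers, whose arrays deviate alike, and the comparisons were not adjusted for their number. For ETP, 1 of 100 splits gave as many genes as the real one at 0.03 µM (14, highest other 4), 0.1 µM (136, highest other 65), 0.3 µM (379, highest other 229), 1 µM (821, highest other 503), 3 µM (1399, highest other 640) and any dose (1321, highest other 158). That 1 was the real split itself, the smallest share 100 splits can give, so such counts were rare among random splits. The same share held for MMS at 100 µM (194, highest other 9), 300 µM (1474, highest other 751), 500 µM (4173, highest other 2559) and any dose (4280, highest other 2433). It also held for QUE at 10 µM (24, highest other 10), 30 µM (1323, highest other 81), 60 µM (2273, highest other 652), 80 µM (2299, highest other 260), 100 µM (2713, highest other 2248) and any dose (3013, highest other 0). At the doses with 0 genes 100 of 100 splits gave as many (highest other 0 or 1), which a count of 0 makes certain, so the splits say nothing of chance there. Where numbers paired the arrays, 1 of the 32 splits that part every pair gave as many genes at MMS 100 µM (highest other 12), MMS 300 µM (744), QUE 10 µM (9) and QUE 30 µM (1202). For the differences, 2 of 100 splits gave as many genes between ETP and MMS (3048, highest other 3112, which exchanged ETP 3 µM number 2) and 1 of 100 between MMS and QUE (2984, highest other 1449). Such counts were thus also rare, though another split gave more genes than the real one between ETP and MMS. Between ETP and QUE 8 of 100 gave as many genes, but a real count of 1 can hardly test chance, so nothing is concluded from it. No splits were drawn for the fit without number 2, which called 2828 genes for this difference. With all arrays the highest other count between ETP and QUE was 1784, in a split that exchanged ETP 3 µM numbers 1 and 2 with QUE 100 µM numbers 2 and 3. This points to a structure of the samples.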
